A study of Mus musculus with 12 samples.

How the data were processed

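Primary mouse aortic vascular smooth muscle cells, the contractile cells of the vessel wall, were grown from aortic explants and used between passages 5 and 8, per the labels' protocols. RNA of 12 libraries was sequenced, in 4 groups of 3: cells in basal medium (control), cells in calcification medium with 3.0 mM sodium phosphate for 7 days, and cells in that medium with either an empty lentivirus (vector) or an αKlotho lentivirus. The labels do not say whether the control and calcification cells without a named vector received any virus. Nor do they say whether the 3 replicates of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

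The authors deposited 1 table of values per gene whose header names samples and no unit. Its values behave as FPKM (fragment numbers scaled by gene length and library size), judged from the deposited values themselves. Multiplied by the exon length of the gene in GENCODE M21, between 98.06% and 98.32% of the values under 100 fragments came out whole in each library, within 0.05 of a fragment, where 10% would by chance. The fragment worth implies a depth between 16644000 and 20015000 fragments per library. A length was found for 99.2% of the 25745 genes. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4 and DESeq2 3.12 were used, with no role given. The counting tool, the annotation and any strand setting are not given in the sources used here, so overlapping and antisense genes and near-identical family members cannot be told apart with certainty. The same notes name both GRCm38 and GRCm39. The table states no build, and only 546 genes have the position that the GRCm38 annotation gives, so coordinates are printed as the table gives them.

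The test planned before the data were examined assumed counts, with limma on log values as the fallback. Since the table holds FPKM, limma 3.58.1 (R 4.3.3) was run with a mean-variance trend on log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 12 libraries were tested, which left 10758. All 12 libraries entered a single fit with 1 coefficient per group, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene is called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Values in FPKM are means ± SD, and errors of log2 fold changes are standard errors (SE).

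Gene lists, 25 in all, were fixed beforehand, and 21 had at least 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Each was tested again with an estimated correlation and with fry. Genes are named by a rule fixed beforehand: 17 genes of the study's question; in each comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between groups; and up to 4 called members per list with the smallest adjusted p. Further called members of a list were named after their values were seen. A gene that the rule names is not reported here.

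The replicate numbers come from the labels, which do not say what they mark. For calcification against control, same-numbered libraries deviated together from their group means (correlations across genes between 0.199 and 0.509), as they did for the Klotho label against calcification (0.573 to 0.731). In these comparisons the value with the replicate number as a block is given where it changes a call. No pair of replicates agreed within sampling noise, and none was merged.

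The fit was tested on simulated data with 10733 genes, of which 100 were changed by each fold size. For calcification against control it recovered 51% of the 2-fold and 88% of the 4-fold changes, with 7 false calls among 146. For the Klotho label against vector it recovered 59% and 95%, with 5 false calls among 159. The simulation drew genes independently, with no shared replicate effect and no trend with GC content or length. The real libraries have both, so these rates may not hold for them. Alternatives covered the pseudocount, the filter, scaling, limma-voom on recovered fragments, the block, fewer libraries, leaving out each library, and a correction for GC content and length.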

Results

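RNA of cultured mouse aortic smooth muscle cells was measured in 4 groups of 3 libraries: basal medium (control), calcification medium, calcification medium with an empty lentivirus, and calcification medium with an αKlotho lentivirus. Calcification medium is rich in phosphate and is used to make such cells deposit mineral. Depth lay between 16644000 and 20015000 fragments per library. The first principal component of log2(FPKM + 1) held 33.0% of the variance and the second 25.9%. On the second, replicate 1 of every group (7.63 to 28.09) lay above all replicates 2 and 3 (-18.57 to 3.12). Contractile genes varied between replicates of each group: Acta2, which encodes smooth muscle actin, stood at 631 ± 404 FPKM in control and 544 ± 399 in calcification medium (SD, n = 3). Acta2 and Myh11 were lowest in replicate 1 of each of the 4 groups.

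Kl, the gene for αKlotho, was examined in every library first, since it checks the label. It was listed at 0 in 11 of the 12 libraries, and replicate 3 of the Klotho group held 1 fragment. A count of 3 fragments would have stood at no more than 0.0193 FPKM in any library, a limit that covers counting error only. The lentivirus group is therefore called the libraries labelled Klotho, and any direction below rests on that label. A transgene whose sequence differs from the mouse gene would not have to be counted here.

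The first comparison asked what calcification medium did to the cells. Several genes that respond to low oxygen fell. Among 32 tested members of the hypoxia and Hif1a target list, 7 fell and none rose, and 29 had a negative fold change, with a median of -0.64. Pgk1 (chromosome X, 105230706 to 105247305), a glycolytic enzyme, went from 578 ± 171 to 194 ± 63.0 FPKM (log2 -1.57 ± 0.26 SE, n = 3 per group, adjusted p = 0.0243). P4ha1, a collagen prolyl hydroxylase subunit, went from 87.0 ± 6.42 to 43.5 ± 2.37 FPKM (log2 -0.98 ± 0.13), and Egln3, a prolyl hydroxylase that marks Hif proteins for degradation, from 4.56 ± 0.97 to 1.21 ± 0.39 FPKM. The lactate exporter Slc16a3 (log2 -2.38), the mitochondrial adenylate kinase Ak4 (-1.65), Pdk1 (-1.24) and Fam162a (-1.26) were the other members called. Adjusted over the list alone, 20 members fell and 1 rose. The list passed camera (adjusted p = 3.99e-24), and adjusted p = 0.0189 with an estimated correlation. With the replicate block 15 members fell, and the list had adjusted p = 0.109 with an estimated correlation.

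**Figure D1:**
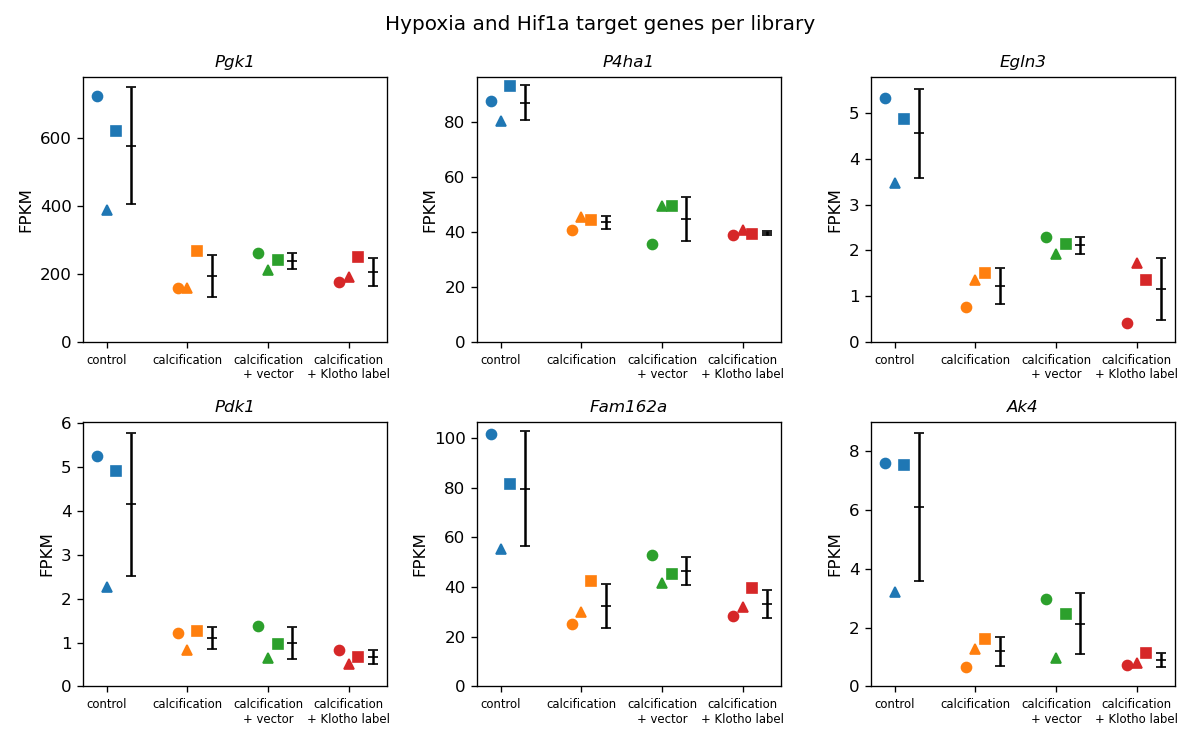
FPKM (vertical axes, linear, from 0) of 6 called hypoxia and Hif1a target genes in the 4 groups (horizontal axis). Circles, triangles and squares are replicates 1, 2 and 3, and the black bars give the mean ± SD, n = 3. In all 6 genes the 3 control libraries lie above the 3 calcification medium libraries.

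Glycolysis genes, some of which are also on the hypoxia list, had a median of -0.58. Of 17 tested, 3 fell (Slc16a3, Pgk1 and Pfkl, log2 -1.40 ± 0.26) and none rose, and 10 fell when adjusted over the list alone, and 6 with the block. The list had adjusted p = 1.32e-09 by camera but adjusted p = 0.303 with an estimated correlation. The largest fall by the rule was that of Ndufa4l2, a mitochondrial protein gene that low oxygen induces, from 41.9 ± 23.0 to 3.49 ± 0.97 FPKM (log2 -3.15 ± 0.43, adjusted p = 0.0083). The matrix genes Col14a1 (56.0 to 16.3 FPKM, log2 -1.85) and Fmod (13.9 to 3.14 FPKM, log2 -1.74) fell too. Hif1a itself had a log2 fold change of -0.34 ± 0.22 (adjusted p = 0.61), Hsp90aa1 -0.05 ± 0.24 and Hsp90ab1 0.11 ± 0.14. Vegfa (-0.73, adjusted p = 0.134) and Slc2a1 (-0.64, adjusted p = 0.225) passed only with the block, at adjusted p = 0.03 and 0.0288.

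All 24 tested cell cycle genes, which act in DNA replication and division, had a positive fold change in calcification medium, with a median of 0.60. Of these, 2 rose: Rrm2, a ribonucleotide reductase subunit, from 42.1 ± 12.6 to 99.3 ± 23.8 FPKM (log2 1.24 ± 0.24, n = 3, adjusted p = 0.0447), and Mcm6, part of the replicative helicase, from 5.32 ± 0.94 to 9.51 ± 0.39 FPKM (log2 0.74 ± 0.13). Adjusted over the list alone 17 rose, and 11 did with the block. The list had adjusted p = 8.6e-14 by camera and adjusted p = 0.303 with an estimated correlation.

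The largest rise by the rule was that of Msln, encoding mesothelin, from 5.28 ± 4.88 to 57.7 ± 42.2 FPKM (log2 3.31 ± 0.65, adjusted p = 0.0457). That call rests on the settings, since it had adjusted p = 0.0503 with a pseudocount of 0.1, and over all settings between 7.28e-06 (block with GC and length correction) and 0.205 (without calcification replicate 2). Mlph, encoding the Rab27a-binding protein melanophilin, rose from 5.87 ± 2.17 to 28.3 ± 3.20 FPKM (log2 2.14 ± 0.23). Ifi209 (log2 2.06), Prl2c3 (1.77) and Havcr2 (1.54), which encodes the receptor Tim-3, rose as well. Ifi209 and Prl2c3 belong to families of near-identical genes, so their values are uncertain. Apcdd1 on the Wnt list (log2 1.21) and Dusp4 on the FGF receptor list (0.93) rose, each the only called member of its list without the block, and neither list passed camera. With the block 2 Wnt genes rose and 2 fell, and 2 FGF receptor genes rose.

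Interferon-stimulated genes gave no call, although all 27 tested had a positive fold change (median 0.82). The list had adjusted p = 1.95e-04 by camera and adjusted p = 0.59 with an estimated correlation, and 6 members rose with the block. Adjusted over the list alone none rose without the block, and 24 did with it. With the block the list had adjusted p = 2.76e-12 by camera and adjusted p = 0.346 with an estimated correlation. Contractile genes gave no call among 20 tested (median -0.20) and 1 rise with the block, with Myh11 at 0.06 ± 1.31, Cnn1 at -0.53 ± 1.22, Tagln at -0.54 ± 0.59 and Acta2 at -0.31 ± 0.91. With the block the SEs of these genes, in the same order, were 0.177, 0.155, 0.159 and 0.222. None of them was called by limma with it (adjusted p = 0.906, 0.096, 0.0957 and 0.522). Adjusted over the contractile list alone with the block, 1 member rose and 3 fell. With all libraries that list did not pass camera without the block (adjusted p = 0.311). It passed with the block (adjusted p = 0.049, and adjusted p = 0.582 with an estimated correlation). Osteochondrogenic genes gave none among 7, and 1 rise and 1 fall with the block. Runx2 stood at 0.15 ± 0.22, Sox9 at -0.29 ± 0.16 and Msx2 at 0.22 ± 0.31. None of these 3 was called by limma with the block (adjusted p = 0.728, 0.228 and 0.581). Mgp, a mineralization inhibitor, stood at -0.16 ± 0.32. Spp1, encoding osteopontin, stood at 1.00 ± 0.54 (adjusted p = 0.536) and passed with the block (adjusted p = 0.0455). Alpl (0.346 FPKM in control, 0.501 in calcification medium) and Bmp2 (0.0437 and 0.199) were below the filter. The lists of other cell types fixed beforehand gave no call without the block: medians were -0.13 for 9 macrophage genes and -0.21 for 12 adventitial fibroblast genes, and fewer than 5 endothelial, adipocyte, Schwann cell or striated muscle markers were tested. With the block 1 fibroblast, 1 adipocyte and 1 striated muscle marker rose and 1 Schwann cell marker fell. The fibroblast list also passed camera with the block (adjusted p = 0.049), and had adjusted p = 0.582 with an estimated correlation.

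The other lists held no called gene without the block. With it 6 extracellular matrix genes, 2 mitochondrially encoded genes, 1 cholesterol synthesis gene and 1 antioxidant gene fell, 1 p53 target and 1 autophagy gene rose, and 2 inflammatory genes rose and 1 fell. Cytosolic chaperones and Hsp90 cochaperones, 30 genes tested, had a median of 0.01 (camera direction down, adjusted p = 0.612). By camera 10 lists passed in all, the remaining 6 being inflammatory genes (median 0.35, adjusted p = 0.0292), p53 targets (0.26, 0.0292), cholesterol synthesis (-0.34, 1.12e-07), extracellular matrix (-0.30, 4.98e-04), mitochondrially encoded (-0.23, 1.35e-04) and endoplasmic reticulum stress genes (-0.13, 0.0344). None of these 6 kept its call with an estimated correlation, the lowest being cholesterol synthesis at adjusted p = 0.303 with an estimated correlation. With replicates 2 and 3 alone the inflammatory median was 0.56, and the endoplasmic reticulum stress list had adjusted p = 0.166. Mineralization inhibitors and phosphate handling (median -0.16), antioxidant genes (0.13), nuclear genes of oxidative phosphorylation (0.08), and autophagy and lysosome genes (-0.04, mean 0.00) did not pass.

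Over all genes, limma called 46 higher and 30 lower in calcification medium than in control, 76 in all and 39 of them by over 1 on the log2 scale. With the replicate block 421 were called, 295 higher and 126 lower, among them all 76. With the 6 libraries alone 3 genes were called, all among the 76, and without the vector libraries 33, of which 31 were among the 76. Single libraries mattered too, with 24, 36 and 21 calls without control replicates 1, 2 and 3, and 15 and 30 without calcification replicates 2 and 3.

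**Figure D2:**
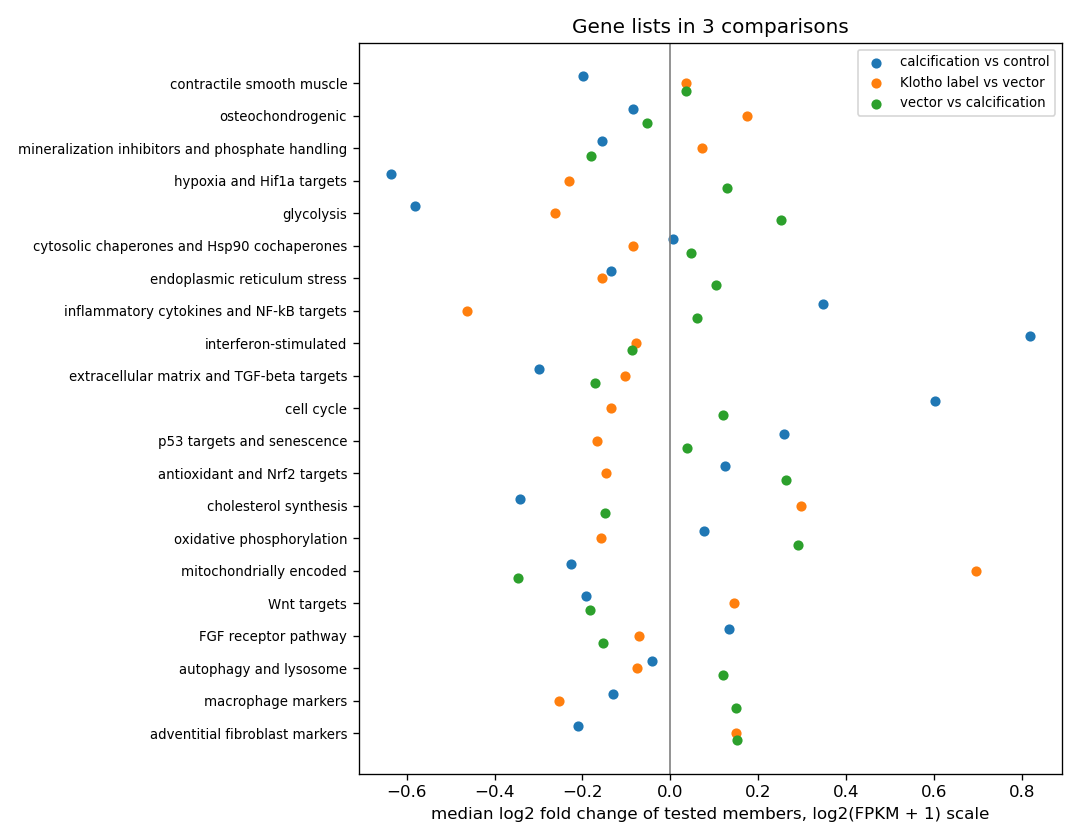
Median log2 fold change of the tested members (horizontal axis, log2(FPKM + 1) scale) of the 21 gene lists with at least 5 tested members (vertical axis), in 3 comparisons marked by colour. In calcification medium against control, the hypoxia list lies at -0.64 and the interferon-stimulated list at 0.82.

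The second comparison asked what the αKlotho lentivirus did against the empty one in calcification medium. No gene passed without the replicate block. Transcripts of the mitochondrial genome had a positive fold change in 12 of 13, with a median of 0.70. These transcripts made up between 2.88% and 3.28% of total FPKM in the libraries labelled Klotho and between 1.53% and 2.05% in the vector libraries. Glycolysis genes had a negative fold change in 17 of 17 (median -0.26), hypoxia targets in 25 of 32 (median -0.23) and inflammatory genes in 16 of 18 (median -0.46). Cholesterol synthesis genes were positive in 17 of 19 (median 0.30).

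Adjusted over the list alone, 9 mitochondrially encoded genes were higher. By camera 8 lists passed: those 5 (adjusted p = 1.97e-07 for the mitochondrial list, 0.00382 for glycolysis, 0.0186 for hypoxia, 0.00571 for inflammation and 0.00321 for cholesterol synthesis), and oxidative phosphorylation (median -0.16), antioxidant (-0.15) and endoplasmic reticulum stress genes (-0.16). None of the 8 passed with an estimated correlation (lowest adjusted p = 0.656) or with fry (lowest adjusted p = 0.111). Among the fixed genes Hif1a stood at 0.45 ± 0.22 (adjusted p = 0.383), Hsp90aa1 at 0.38 ± 0.24, Hsp90ab1 at -0.10 ± 0.14, Vegfa at -0.45 ± 0.18 (adjusted p = 0.309) and Slc2a1 at -0.26 ± 0.19. Runx2 (0.18 ± 0.22), Sox9 (0.28 ± 0.16), Msx2 (-0.07 ± 0.31), Spp1 (0.21 ± 0.54), Mgp (-0.09 ± 0.32), Acta2 (-0.05 ± 0.91), Myh11 (0.37 ± 1.31), Tagln (0.02 ± 0.59) and Cnn1 (-0.05 ± 1.22) did not pass either. With the block, which was not taken to pair these libraries, the SEs of Acta2, Myh11, Tagln and Cnn1 were 0.222, 0.177, 0.159 and 0.155. None of these contractile genes was called by limma with it (adjusted p = 0.926, 0.268, 0.956 and 0.877). Alpl (0.541 and 0.726 FPKM) and Bmp2 (0.101 and 0.166) were below the filter.

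With replicates 2 and 3 alone the glycolysis list had a median of -0.07 (adjusted p = 0.392), hypoxia -0.16 (0.06), antioxidant -0.08 (0.195), oxidative phosphorylation -0.07 (0.142) and cholesterol synthesis 0.12 (adjusted p = 0.0269). With GC and length corrected, the hypoxia median was -0.11 (adjusted p = 0.0134), antioxidant -0.08 and endoplasmic reticulum stress -0.10 (adjusted p = 0.106 for both), and oxidative phosphorylation -0.10 (adjusted p = 0.00165). The mitochondrially encoded median was then 0.475 (camera adjusted p = 3.44e-06) and the inflammatory one -0.362 (0.00165). Glycolysis stood at -0.233 (0.0134) and cholesterol synthesis at 0.232 (3e-04). With limma 0 genes were called, where 1514 had an unadjusted p under 0.05 and 538 would by chance. limma-voom also called 0. Fold changes in this comparison followed gene properties across genes, with a correlation of -0.521 with GC content and 0.419 with log2 length (genes are not independent replicates), and 807 genes were under that unadjusted level once both trends were removed.

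The third comparison gave the background of the virus: empty vector against calcification medium alone. Nuclear genes of oxidative phosphorylation had a positive fold change in 26 of 27 (median 0.29), glycolysis genes in 15 of 17 (0.25) and antioxidant genes in 19 of 22 (0.26). Mitochondrially encoded transcripts had a negative one in 12 of 13 (median -0.35). These 4 lists passed camera (adjusted p = 1.13e-07 for oxidative phosphorylation and 0.036 for each of the others), and each had adjusted p = 0.855 with an estimated correlation. Oxidative phosphorylation had a median of 0.19 (adjusted p = 3.94e-07) with GC and length corrected and 0.17 (adjusted p = 6.56e-05) with replicates 2 and 3 alone. Glycolysis had 0.20 (adjusted p = 0.0549) and 0.06 (0.89), and antioxidant genes 0.12 (0.123) and 0.11 (0.137), in the same order. Interferon-stimulated genes had a median of -0.09. limma and limma-voom called 0 genes, with 1520 at an unadjusted p under 0.05 by limma, and fold changes correlated with GC content (0.397) and log2 length (-0.536) across genes.

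The libraries labelled Klotho against calcification medium alone gave 0 calls by both tools. By limma 337 genes were at an unadjusted p under 0.05, and 558 with the replicate block, where chance gives 538. By camera 6 lists passed. Mitochondrially encoded genes were positive in 12 of 13 (median 0.36, adjusted p = 4.62e-07), oxidative phosphorylation genes in 20 of 27 (0.10, 0.00538) and cholesterol synthesis genes in 14 of 19 (0.05, 0.0216). Inflammatory genes were negative in 18 of 18 (median -0.35, adjusted p = 1.58e-04), extracellular matrix genes in 25 of 29 (-0.20, 0.0109) and FGF receptor genes in 12 of 14 (-0.17, 0.0212). None passed with an estimated correlation (lowest adjusted p = 0.73) or with fry (lowest adjusted p = 0.891). With the block 9 lists passed. The 3 added were interferon-stimulated genes (median -0.19, adjusted p = 0.758 without and 0.0368 with the block), p53 targets (-0.08, 0.127 and 0.0464) and adventitial fibroblast markers (0.12, 0.0702 and 0.00533). With the block the lowest was adjusted p = 0.582 with an estimated correlation. No list member was called, with or without the block.

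The last question was whether genes moved by calcification medium went the other way in the libraries labelled Klotho against vector. Of the 76 called genes, 45 had the opposite sign (59.2%, exact binomial 95% interval 47.3% to 70.4%, which treats genes as independent), against 63.4% of all genes. The 2 comparisons share no library. The 46 higher genes had a median of -0.10 in the second comparison (camera p = 0.0322, and p = 0.124 with an estimated correlation), and the 30 lower genes a median of 0.09 (camera p = 0.585). Without the block no gene was called in the second comparison, so none was called in both. Fold changes of the 2 comparisons followed GC content and log2 length with opposite signs. Correlations across genes were 0.199 and -0.137 in the first, and -0.521 and 0.419 in the second. With both trends removed, the share of opposite signs among the genes then called was 53.2%, and 56% with the block as well. In the libraries labelled Klotho against calcification medium alone, 47 of the 76 had the opposite sign (61.8%), against 55.2% of all genes. That comparison shares the calcification libraries with the first, so their fold changes are not independent.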

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

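Added after the data were seen were the 2 FPKM scalings, the filter on 3 libraries, the GC and length corrections, replicates 2 and 3 alone, the block with an estimated correlation and the fits without vector libraries; the others were planned. The planned DESeq2 test, DESeq2 size factors, upper-quartile scaling of counts and CPM filter were not run, because the deposited values are not counts. Fragments recovered from those values were used for limma-voom, and the planned count methods were not tried on them. Calcification against control gave 76 calls and between 59 and 94 with the other pseudocounts, scalings, limma-voom, the GC and length correction, the filter on 3 libraries and replicates 2 and 3 alone. Of the 59 called with replicates 2 and 3 alone, 31 were among the 76. The same comparison gave 37 with no filter on low values, 421 with the replicate block, 575 with the GC and length correction and that block, 3 with the 6 libraries alone and 33 without the vector libraries. Leaving out 1 library gave between 15 and 60. More or fewer genes tested, or fewer libraries, change these counts by construction; the cause was not tested for the block. The Klotho label against vector had 0 calls but 2 with no filter and 11 with the replicate block, and 0 with that block and the GC and length correction; vector against calcification had 0 but 1 with no filter; the Klotho label against calcification had 0 but 4 with replicates 2 and 3 alone. For the first 2 of these 1 of the 3 same-numbered pairs did not deviate together (correlations from -0.063 to 0.522), so the numbers were not taken to pair the libraries, although all 12 libraries correlated best with their own number. With the block in both comparisons, 272 of the 421 genes had the opposite sign in the Klotho label against vector (64.6%, against 63.4% of all genes). Camera gave p = 0.00476 for the 295 higher and p = 0.00412 for the 126 lower genes, both toward the opposite sign (p = 0.147 and p = 0.201 with an estimated correlation). Called in both were 3 genes, all with opposite signs, where independent lists would share 0.176 with opposite signs. Fold changes of all genes correlated at -0.285 between these comparisons, so the lists are not independent. With the GC and length correction and the block no gene was called in both. The share of opposite signs was 45.9% with no filter, and 43.3% to 75% leaving out 1 library. Lists passing camera numbered 10, 8 and 4 in the first 3 comparisons; with an estimated correlation 1, 0 and 0, with fry 1, 0 and 0, and with the replicate block and an estimated correlation 0, 0 and 0. The GC and length correction left 2 of the 4 for vector against calcification. The hypoxia list in calcification medium was the one that held with both the estimated correlation and fry. Of 19 called named genes, no setting reversed a sign; between 4 and 12 stayed called when 1 library was left out, 17 with limma-voom and 1 with the 6 libraries alone. Of the 28 fold changes of uncalled named genes in 2 comparisons, 15 changed sign under some setting. Besides the calls given in the report, the block changed no camera call of a list and no call of a named gene in calcification against control or in the Klotho label against calcification. Depth limits mainly genes below the filter, such as Alpl and Bmp2.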

Other observations

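The tests of a single replicate set, control culture density, an interferon response, the 3 explanations for Kl, the splits for calcification against control and the marker lists below were chosen after the results were seen, as was the second simulation.

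Immediate early genes, which cells switch on within minutes of a stimulus, were lower in the libraries labelled Klotho than in calcification medium alone in 17 of 17 tested (median -0.35). Ier2 stood between 13.48 and 14.59 FPKM in those 3 libraries and between 21.53 and 30.86 in calcification medium, and Zfp36 between 15.33 and 17.0 against 22.86 to 23.91. In control Ier2 stood between 13.22 and 17.3 FPKM. The list had adjusted p = 1.15e-13 by camera over 8 tests and adjusted p = 0.0136 with an estimated correlation, but 0.0618 with the block as well. No member passed alone in that comparison, and the list was written after some of these genes had been seen to be low, so it is not independent evidence. Against vector the median was -0.42 (adjusted p = 1.88e-05 by camera, and adjusted p = 0.1 with an estimated correlation). In calcification medium against control 15 of 17 were positive (median 0.22, adjusted p = 0.00712 by camera, and adjusted p = 0.256 with an estimated correlation), and Ier2 was the member called without the block (log2 0.80 ± 0.16, adjusted p = 0.0447).

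Control replicate 2 had 14969 genes above 0, where the other 11 libraries had between 17343 and 19361.

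Msln and Upk1b (12.2 to 41.0 FPKM, adjusted p = 0.16, and 0.00067 with the block) are markers of mesothelium, the lining of body cavities, and a candidate source was mesothelial cells in the cultures. Of 14 listed markers 4 were tested. Besides Msln and Upk1b, which prompted the list, these were Upk3b and Krt19, with a median of -0.09. The 4 together had adjusted p = 0.0374 by camera (0.0102 with the block), and adjusted p = 0.256 with an estimated correlation (0.118 with the block). Below the filter, Krt7 went from 0.208 to 1.18 FPKM, Krt18 from 0.0811 to 0.349 and Lrrn4 from 0 to 0.152. Lower in calcification medium were Gpm6a (1.21 to 0.549), Cldn15 (0.704 to 0.424), Rspo1 (0.28 to 0.136) and Bnc1 (0.839 to 0.762). Wt1 was at 0.00283 and Muc16 at 0.00149 in calcification medium, both at 0 in control. Since 2 low markers decide little, the hypothesis stays open. The protocol removed the adventitia and endothelium, and names no step against mesothelium.

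Hypoxia and Hif1a targets were lower in calcification medium than in control (median -0.64, and -0.77 to -0.55 leaving out 1 library). Removing each library's trend with GC content and length left the median at -0.684 (-0.78 to -0.59 leaving out 1 library), which argues against such a bias as the whole cause. A single replicate set is not needed either: the medians in the same-numbered pairs were -0.877, -0.487 and -0.624. Control cultures that were denser or had less oxygen may give the same pattern; the cell cycle median of 0.603 does not decide this, and the table records neither oxygen nor density. The medium itself is the biological explanation the design names, and it stays open beside that one.

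The Klotho label against vector and vector against calcification had 1514 and 1520 genes at an unadjusted p under 0.05, but no called gene without the block. Leaving out 1 library moved the first count to between 923 and 1874 and the second to between 703 and 2527. A split mixing the groups exceeded the second count (1619) but not the first (highest other 928), so the second count does not set the vector libraries apart. On the first principal component vector replicate 1 lay far out (31.54). Vector replicates 2 and 3 (17.13 and 15.82) lay near replicate 3 of calcification medium (14.2) and of the Klotho label (13.06). After the GC and length correction 807 remained in the first, fewer than before and more than the 538 of chance, which lies between the bounds set in advance for and against this explanation, so part of the pattern may be such a bias. With the block, which was not taken to pair these libraries, that comparison had 2162 before the correction and 1379 after it. An interferon response to virus was not seen, with a list median of -0.088, but leaving out 1 library moved it from -0.34 to 0.23. Both comparisons share the vector libraries: the covariance of their fold changes was -0.0618 (correlation -0.776), within the range of 100 simulations of unchanged groups drawn with replacement (mean -0.0328, -0.146 to 0.0385) and of 100 drawn without (mean -0.0227, -0.0844 to 0.0186), and 3 vector libraries are too few to split. An effect of the empty virus itself, a library batch and these explanations cannot be told apart here.

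Kl RNA was missing from the libraries labelled Klotho. Low depth does not account for it, since 3 fragments would stand at 0.0182 FPKM or less in these libraries. Neither does a swap with another group if the transgene is counted as Kl, as no library held more than 1 Kl fragment. If the transgene is not counted as Kl, these values cannot show whether groups were swapped. A transgene of another species or with a recoded sequence could escape a table of mouse genes; the 1 fragment in these libraries does not decide between that and cells without the transgene. A mix-up with samples outside the series was not tested.

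Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For calcification against control 1 split, the real one, gave 76 calls or more, and the highest other gave 1. By genes at an unadjusted p under 0.05, 2 splits reached its 1239, and the highest other gave 1267, with both replicates 1 and calcification replicate 3 on the same side. Of the 4 splits that part all 3 replicate pairs, the other 3 gave 0, 1 and 1 calls (236, 132 and 791 genes at that level), and those that part 1 pair gave 0 calls. Counting genes at that level, 1 split reached the 1514 of the Klotho label against vector (highest other 928), and 2 reached the 1520 of vector against calcification (highest other 1619, with calcification replicates 1 and 2 beside vector replicate 3). For the Klotho label against calcification 6 splits reached 337, and the highest other gave 2299, with both replicates 1 and calcification replicate 2 on the same side, which points to a structure of the samples by replicate number. Among its 4 splits that part all 3 pairs, the other 3 gave 63, 63 and 122.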
